A study of Rattus norvegicus with 20 samples.

How the data were processed

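Total RNA of whole mesenteric artery from 20 rats was labelled with Cy3 and hybridised to Agilent 60-mer rat arrays of 62976 features, 1 sample per array, per the labels and the file headers. The 5 groups of 4 arrays were taken from the sample titles: untreated WKY, WKY with 2K1C, WKY with 1K1C, SHR and SHRSP, all of Izm colonies. The labels do not settle whether the age of 6 weeks is that at operation or at sampling. The signal intensity of each spot was produced by Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes; the processed signal is background-subtracted by that software, per the file headers, and on a linear scale. The deposited value table held the same processed signal intensity, equal for every spot and array to a largest relative difference of 0, with medians of 59.7 to 133 per array and no scaling between arrays. Its scale, linear, and its centring, none, follow from that match, and single-channel values have no direction.

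The main values were log2 of the processed signal minus the array's 75th percentile over non-control spots, which ran from 574.5 to 1193. The 4259 control spots and spots marked as outliers (301 to 684 per array) were left out. No spot was saturated. Spots of a probe were averaged, leaving 30367 distinct probes. Probe names came from the files; 18355 probes (60.44%) had an accession that matched a current rat symbol in a RefSeq table, 2935 of them with an updated name, and the other 12012 kept the files' name. Coordinates are those of the array design on rn4. A probe was kept where it was well above background on all 4 arrays of at least 1 group (18899 probes), and for each gene name the probe with the highest mean over the 20 arrays was tested (16424 genes). Log2 values of all 5 groups were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with a prior of 2.57 degrees of freedom and Benjamini-Hochberg adjustment over the genes of a comparison at 0.05. Where a probe was not well above background on any array of a group, "at least" gives the brighter group's mean over the dimmer group's mean of, per array, the lowest signal among probes well above background or the probe's own signal where that is higher.

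There were 7 comparisons: SHR, SHRSP, 2K1C and 1K1C against untreated WKY, SHRSP against SHR, 1K1C against 2K1C, and the mean of the inherited forms against the mean of the renovascular forms. The 30 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Of these, 29 had at least 3 measured members, and of the 5 sex-linked transcripts 0 were measured. The lists covered smooth muscle, endothelium, lymphatic endothelium, white and brown adipocytes, fatty acid oxidation, extracellular matrix, the renin-angiotensin system, endothelin, nitric oxide and natriuretic peptides, ion channels, adrenergic receptors, redox enzymes, macrophages, lymphocytes, cytokines, interferon response, antigen presentation, cell cycle, circadian clock, immediate early and glucocorticoid responses, cholesterol synthesis, chaperones, blood pressure or cardiac trait genes, erythroid cells, mesothelium, pancreas and intestine, striated muscle and nerve. A neuron list and a noradrenergic neuron list were added after the data were seen, with some members already known to differ.

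Genes were named by a rule set before the data were examined. For each comparison of 2 groups it took the 8 largest differences in each direction among called genes with a symbol, with groups that did not overlap and with the brighter group well above background on all arrays. It added up to 4 called members of each list with a called shift and up to 2 of every other list, or, where a list had no called member, up to 2 members with the largest difference. Renin-angiotensin genes and a few others were fixed by name, and members of a count of 5 or fewer were named, which covers the unnamed transcript in 2K1C and the called list members of the comparison of inherited with renovascular forms, chosen after their values were seen. Some genes that the rule takes are not reported here. Calls shared by comparisons with the same controls were set beside 20 simulations of unchanged groups and beside split controls.

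The arrays lay on 3 slides, each scanned at its own time: slide 1 held 2K1C, slide 2 1K1C and untreated WKY, and slide 3 SHR and SHRSP. Only 1K1C against untreated WKY and SHRSP against SHR lay within a slide. In both, each group had its own row of the slide, so group and row cannot be told apart. Row 1 held 1K1C or SHR, and row 2 untreated WKY or SHRSP. The mean net signal of negative controls was 26.8 to 27.6 on slide 1, 31.9 to 38.4 on slide 2 and 34.5 to 37.4 on slide 3. Within groups, correlations between arrays over the tested genes ran from 0.934 to 0.995. Alternatives were quantile normalization, normexp with an offset of 50 and quantile normalization, scaling to the array median, the deposited value table, no detection filter, detection on all 20 arrays, every probe tested by itself, eBayes with trend and robust options, array weights, the replicate number or the slide as a block, a fit of the compared groups alone, a 2-fold minimum, camera with an estimated correlation, and leaving out each array in turn. On data simulated from the means and spreads of the 16424 genes, with independent noise and 200 genes changed in SHR against untreated WKY, the fit recovered 52% of genes changed by 1 on the log2 scale and 88% of those changed by 2, with 10 false calls. Figures were drawn with matplotlib 3.10.9.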

Results

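Total RNA of the mesenteric artery, a resistance vessel bed that supplies the intestine, was profiled on 20 single-colour Agilent rat arrays. The arrays fell into 5 groups of 4 rats. Spontaneously hypertensive rats (SHR) and their stroke-prone substrain (SHRSP) carry inherited hypertension. Wistar-Kyoto rats (WKY) are the normotensive strain, and were either left without operation or had a renal artery narrowed, an operation meant to cause hypertension. No blood pressure was examined here, so groups are called hypertensive by their strain or operation. The 2-kidney, 1-clip operation (2K1C) leaves the other kidney in place, and the 1-kidney, 1-clip operation (1K1C) removes it. All rats were labelled as 6 weeks old, with 3 weeks for the operation. The labels call the arrays biological replicates. Between 66.5% and 71.7% of the non-control spots of an array lay well above background, and 16424 genes were tested. The number of arrays limits the precision of each value. In the text, log2 differences are given with their SE, levels are log2 signals relative to the array's 75th percentile with their SD, n = 4 arrays per group, and a gene is called where limma's Benjamini-Hochberg adjusted p is under 0.05.

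The 1st question was how arteries of the hypertensive strains differ from those of untreated WKY. In SHR the signal of Vegfb, a growth factor of the vascular endothelial family, was at least 199-fold lower than in WKY (adjusted p = 9.41e-12), with the probe not well above background on any SHR array. The signal of Endog, which encodes mitochondrial endonuclease G, was lower by 2.13 ± 0.20 on the log2 scale, at -1.97 ± 0.30 against 0.15 ± 0.25. Afp, the fetal plasma protein alpha-fetoprotein, was at least 15.2-fold higher in SHR and not well above background in WKY (adjusted p = 3.83e-09). The orphan receptor gene Gpr35 rose at least 4.75-fold. C4bpa, a regulator of complement, differed by -4.16 ± 0.67 with 1 of 4 SHR arrays well above background, and the thioesterase gene Acot5 was at least 3.37-fold lower. Each of these 6 genes was called whichever single array was left out. None had another detected probe, so a probe effect and a change in RNA cannot be told apart. SHR also lay on another slide than untreated WKY.

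In all, 303 genes were called between SHR and untreated WKY, 137 higher and 166 lower in SHR, against 2294 at an unadjusted p under 0.05 and 821 expected there by chance. The split moved to 181 higher and 128 lower with quantile normalization, 192 and 127 with normexp, and 221 and 118 with scaling to the array median. The count depended on single arrays: it was 151 without untreated WKY replicate 2, 124 without replicate 3 and 669 without replicate 4, and 548, 137, 126 and 136 without SHR replicates 1, 2, 3 and 4. There were 7659 genes with array weights, 120 from the deposited values, and 102 in a fit of these 2 groups alone.

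Among the lists fixed before the data were examined, immediate early genes, which are induced within minutes by growth factors or stretch, were shifted upward in SHR (median 0.92, all 17 measured members higher, 1 called and 3 adjusted over the list alone; camera adjusted p = 0.000155, and 0.444 with an estimated correlation). Its called member Zfp36, which destabilises cytokine mRNAs, rose by 1.69 ± 0.34 and lost its call without untreated WKY replicates 1 or 3 or SHR replicates 2, 3 or 4 (adjusted p up to 0.0618). Glucocorticoid-responsive genes were shifted upward too (median 0.55, 10 of 12 higher, 1 called and 6 adjusted over the list alone; adjusted p = 0.000155, and 0.0839 with an estimated correlation), with the receptor tyrosine kinase feedback inhibitor Errfi1 up by 2.14 ± 0.42. Errfi1 lost its call without untreated WKY replicate 3 or SHR replicates 2, 3 or 4 (adjusted p up to 0.0599). Endothelial markers (median 0.46, 13 of 15 higher, 1 called and 4 adjusted over the list alone; adjusted p = 0.0032) and chaperone genes of heat shock and the endoplasmic reticulum (median 0.27, 14 of 16 higher, 0 called and 2 adjusted over the list alone; adjusted p = 0.00389) also shifted upward. These lists gave adjusted p = 0.852 and adjusted p = 0.444 with an estimated correlation. The chaperone shift was not called without untreated WKY replicate 4 (adjusted p = 0.0572).

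Erythroid genes (median -1.01, 6 of 6 lower, 0 called and 2 adjusted over the list alone; adjusted p = 0.00331) and brown adipocyte genes (median -0.80, 8 of 8 lower, 1 called and 2 adjusted over the list alone; adjusted p = 0.00494) were shifted downward in SHR. Their adjusted p values with an estimated correlation were 0.852 and 0.472, and the brown adipocyte shift was not called without untreated WKY replicate 1 (adjusted p = 0.0886), the array with the highest brown adipocyte score of its group, 2.75. Extracellular matrix genes (median 0.36, 0 of 25 called; adjusted p = 0.0222, and 0.881 with an estimated correlation) were not called without untreated WKY replicate 3 or SHR replicates 2 or 3 (adjusted p up to 0.13). Pancreas and intestine markers (median 1.85, 0 of 9 called; adjusted p = 0.0222, and 0.881 with an estimated correlation) ranged from -4.80 to 2.54 within untreated WKY, and lost their call without untreated WKY replicates 2 or 3 or SHR replicate 2 (adjusted p up to 0.43). Called members of lists whose shift was not called included sulfiredoxin (Srxn1) at -1.24 ± 0.26, Gstt1 at 1.22 ± 0.28, the chemokine gene Cxcl9 at -1.16 ± 0.26, the adhesion molecule gene Selp at 1.63 ± 0.36 and the clock repressor Nfil3 at 1.69 ± 0.33. Srxn1 lost its call without untreated WKY replicates 1 or 2 or SHR replicates 2, 3 or 4, Gstt1 without untreated WKY replicates 1, 2 or 3 or SHR replicate 4, Cxcl9 without untreated WKY replicate 2 or SHR replicates 2, 3 or 4, and Nfil3 without untreated WKY replicate 3 (adjusted p up to 0.0818, 0.0964, 0.111 and 0.0554). Selp lost its call without untreated WKY replicates 2 or 3 or SHR replicates 2, 3 or 4 (adjusted p up to 0.105).

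In SHRSP the signal of Hba-a3, an alpha globin gene, was at least 63.8-fold lower than in untreated WKY (adjusted p = 1.11e-08). That of Ephx2, the soluble epoxide hydrolase that degrades vasodilator epoxides of arachidonic acid, was at least 29.9-fold lower (adjusted p = 3.12e-06). Agtrap, which encodes a protein that binds the angiotensin II type 1 receptor, differed by -4.80 ± 0.15, from 0.12 ± 0.31 to -4.68 ± 0.31. Samd14 was at least 5.57-fold lower, and Endog was lower by 2.12 ± 0.20. Afp was at least 18.2-fold higher, Gpr35 at least 5.21-fold and Pip at least 2.75-fold. The matricellular gene Ccn1 rose 9.42-fold and the G-protein regulator gene Rgs11 5.53-fold. Each of these 10 genes was called whichever single array was left out. The limits of a single probe and of another slide hold here too.

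The plot of 6 genes shows that the signals of Vegfb in SHR, and of Hba-a3, Agtrap and Ephx2 in SHRSP, lay apart from those of all other groups. On the rn4 build the probes lie on chromosome 1 from 209657830 to 209657889 for Vegfb and chromosome 10 from 15559461 to 15559520 for Hba-a3, per the array's annotation. Those of Agtrap and Ephx2 lie on chromosome 5 from 165154364 to 165154423 and chromosome 15 from 45535737 to 45538220.

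**Figure D1:**
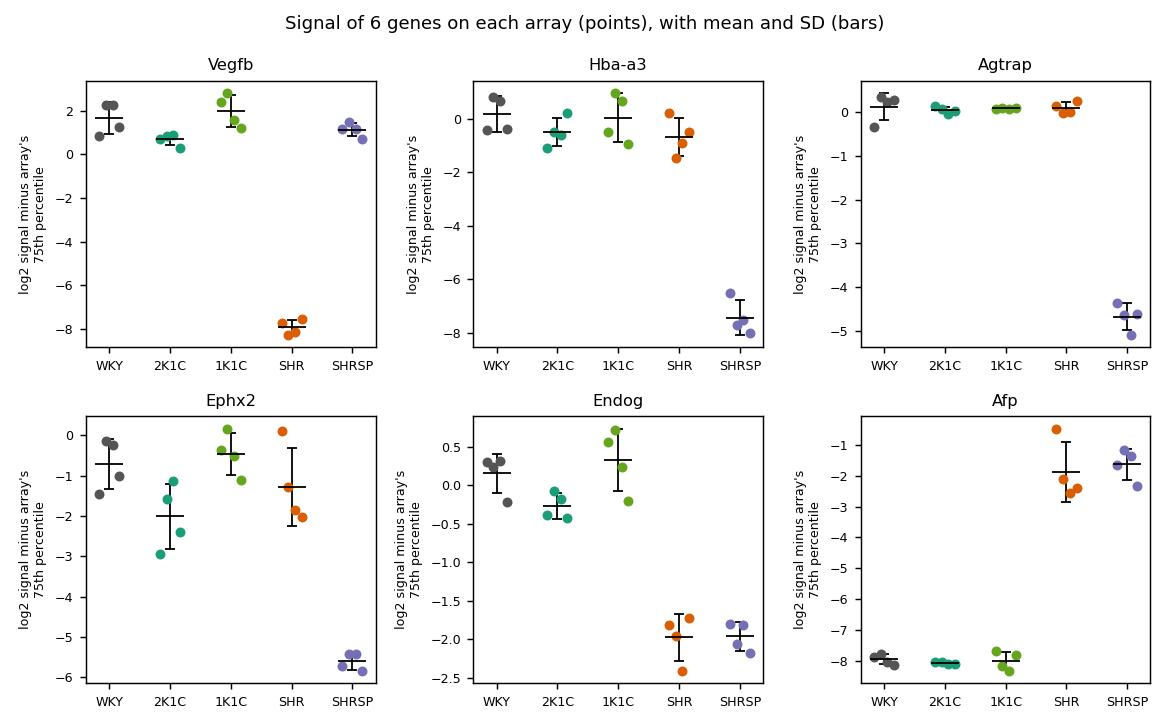
Log2 signal relative to the array's 75th percentile (y axis) of 6 genes in untreated WKY, 2K1C, 1K1C, SHR and SHRSP (x axis), with 1 point per array and bars for the mean and SD of 4 arrays. The probes of Vegfb in SHR, Hba-a3 and Ephx2 in SHRSP and Afp in untreated WKY were not well above background on any array, so those points show background signal. Agtrap stood at -4.68 in SHRSP against 0.12, and Endog and Afp differed from untreated WKY in both hypertensive strains.

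Between SHRSP and untreated WKY 393 genes were called, 189 higher and 204 lower, with 2735 at an unadjusted p under 0.05. The deposited value table gave 143 higher and 64 lower. Without untreated WKY replicates 2, 3 and 4 in turn the count was 220, 172 and 911, and without SHRSP replicates 1, 2 and 3 it was 213, 213 and 191. Array weights gave 5540 genes, and a fit of these 2 groups alone 161.

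Cell cycle genes were shifted upward in SHRSP (median 0.65, 23 of 24 higher, 2 called and 10 adjusted over the list alone; camera adjusted p = 5.02e-08), as were immediate early genes (median 1.38, 16 of 17 higher, 1 called and 10 adjusted over the list alone; adjusted p = 1.34e-06). These gave adjusted p = 0.59 and adjusted p = 0.332 with an estimated correlation. The called cell cycle members were Cdc20 at 0.62 ± 0.14 and Plk1 at 0.83 ± 0.21, both regulators of mitosis; Cdc20 kept its call only without untreated WKY replicate 4 or SHRSP replicate 4, and Plk1 only without untreated WKY replicate 4 (adjusted p up to 0.114 and 0.175). Brown adipocyte genes were shifted downward (median -0.99, 8 of 8 lower, 0 called; adjusted p = 0.011, and 0.535 with an estimated correlation). Extracellular matrix genes were shifted upward (median 0.40, 20 of 25 higher, 0 called, 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.011, and 0.833 with an estimated correlation), and were not called without untreated WKY replicate 3 (adjusted p = 0.0511). Elastin (Eln), not called, was at 2.56 ± 0.85. It was also at 2.59 in 2K1C and 0.98 in 1K1C against untreated WKY. Genes proposed for blood pressure or cardiac traits in these strains were shifted downward (median -0.33, 10 of 15 lower, 2 called and 3 adjusted over the list alone; adjusted p = 0.0151, and 0.332 with an estimated correlation), the called members being Ephx2 and Endog, and were not called without untreated WKY replicate 4 (adjusted p = 0.069). Srxn1 at -1.41 ± 0.26 and Cxcl9 at -1.38 ± 0.26 were again lower, and were called whichever single array was left out. Of 14 clock genes 2 were called higher and 1 lower. Npas2, called higher, was at 0.8 ± 0.2, but its other detected probe differed by 0.02. Nfil3 was at 1.41 ± 0.33 and not called without untreated WKY replicates 2 or 3 or SHRSP replicates 3 or 4 (adjusted p up to 0.122). Nr1d1 was at -2.03 ± 0.44 and not called without untreated WKY replicates 2 or 3 or SHRSP replicate 4 (adjusted p up to 0.0772).

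Endothelial markers (median 0.41, 12 of 15 higher, 1 called; adjusted p = 0.0151), chaperone genes (median 0.29, 12 of 16 higher, 0 called; adjusted p = 0.0151) and erythroid genes (median -0.73, 6 of 6 lower, 0 called; adjusted p = 0.0386) shifted the same way as in SHR. With an estimated correlation each gave adjusted p of 0.523 or more. The endothelial shift was not called without untreated WKY replicates 1 or 3 or SHRSP replicate 3 (adjusted p up to 0.0823), the chaperone shift without untreated WKY replicate 4 or SHRSP replicate 3 (0.107), and the erythroid shift without untreated WKY replicates 2, 3 or 4 or SHRSP replicates 3 or 4 (0.379).

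A pair of nerve genes differed between untreated WKY and both strains. Peripherin (Prph), an intermediate filament of peripheral neurons, was at -3.50 ± 0.85 in SHR and -3.51 ± 0.85 in SHRSP, and the growth cone gene Gap43 at -2.97 ± 0.70 and -3.02 ± 0.70. Both genes varied widely within untreated WKY (Prph 2.04 ± 2.34 and Gap43 0.71 ± 2.03). In SHR both calls were lost without any single array except untreated WKY replicate 4 (adjusted p up to 0.137 and 0.116). The same held for Prph in SHRSP (0.116), while Gap43 there was called without untreated WKY replicates 1 or 4 only (0.0879). The neuronal splicing factor gene Rbfox1 was at -3.82 ± 0.73 in SHRSP and was called whichever single array was left out. Its level was 0.77 on untreated WKY replicate 1, the array with the highest neuron score, 5.38, and -5.42 to -4.18 in 1K1C, also WKY. In the list of Schwann cell and nerve genes 2 of 9 members were called lower in each strain, and the list's medians of 0.08 and 0.55 were above 0 while its means of -0.61 and -0.32 were below 0, with no called shift (adjusted p = 0.255 and 0.493).

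SHR and SHRSP shared 189 genes called the same way against untreated WKY, 90 higher and 99 lower, with 0 called in opposite ways. Lists drawn independently would share 1.58 higher and 2.06 lower, and unchanged groups simulated against the same controls shared 0 in each of 20 simulations. That 0 was nearly set in advance, because groups without an effect have few calls to share. It does not measure what shared controls or a shared slide add to the overlap. With different pairs of untreated WKY arrays as the controls of each strain, 55 to 68 genes were shared. Across genes, which are not independent replicates, the log2 differences of the strains had a correlation of 0.84 (0.50 in simulation) and a covariance of 0.262 (0.059 in simulation). With different pairs of untreated WKY arrays as controls the correlation was 0.307 to 0.64. The shared count was 101, 87 and 497 without untreated WKY replicates 2, 3 and 4, and 100, 93 and 111 without SHR replicates 2, 3 and 4. It was 110, 113 and 110 without SHRSP replicates 1, 2 and 3. It was 4583 with array weights, 79 from the deposited values and 57 in fits of the compared groups alone. The SHR and SHRSP arrays were on a slide of their own, so strain and slide cannot be told apart in these comparisons.

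The 2nd question was how SHRSP differs from SHR, a comparison within 1 slide. SHR lay in row 1 of that slide and SHRSP in row 2, so strain and row cannot be told apart. Vegfb was at least 139-fold higher in SHRSP (adjusted p = 1.24e-11), and Agtrap differed by -4.78 ± 0.15 (adjusted p = 1.52e-12). Hba-a3 was at least 35.7-fold lower, while the 6 measured erythroid genes of the fixed list had a median of 0.17 (adjusted p = 0.416). Ephx2 was at least 20.2-fold lower, Micb at least 6.76-fold, Samd14 at least 2.48-fold and Zfp108 at least 1.97-fold lower. Alpha-sarcoglycan (Sgca), part of the dystrophin complex of muscle, differed by -1.67 ± 0.22. The zinc finger gene Zfp597 rose 7.09-fold, Rgs11 4.61-fold, the peroxisomal membrane gene Pxmp4 3.63-fold and Serhl2 3.60-fold, and the transporter gene Abca9 rose at least 2.46-fold. Each of these 13 genes was called whichever single array was left out. None had another detected probe, so a probe effect and a change in RNA cannot be told apart. Of the other named genes, Pcdhga8 (1.91 ± 0.35), Rhd (1.90 ± 0.37) and Depp1 (-1.75 ± 0.31) each lost their call without some single array, at adjusted p up to 0.0641, 0.122 and 0.0649. These arrays were SHR replicates 1 and 4 and SHRSP replicate 1 for Pcdhga8, SHR replicates 2, 3 and 4 and SHRSP replicates 1, 2 and 3 for Rhd, and SHR replicate 4 and SHRSP replicates 1 and 2 for Depp1.

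Cell cycle genes were shifted upward in SHRSP (median 0.80, all 24 higher, 0 called and 12 adjusted over the list alone; camera adjusted p = 2.77e-25, and 0.106 with an estimated correlation). Members such as Bub1b (1.21 ± 0.32) and Top2a (0.96 ± 0.32) were not called singly. Glucocorticoid-responsive genes were shifted downward (median -0.63, all 12 lower, 1 called and 3 adjusted over the list alone; adjusted p = 1.89e-09), and this list alone was also called with an estimated correlation (adjusted p = 0.0032). Its called member Tsc22d3, the glucocorticoid-induced leucine zipper, was at -0.90 ± 0.18, and not called without SHR replicates 3 or 4 or SHRSP replicates 1, 2 or 3 (adjusted p up to 0.126). Interferon-stimulated genes (median 0.23, all 19 higher, 0 called; adjusted p = 2.39e-05) and cholesterol synthesis genes (median 0.26, all 17 higher, 0 called and 1 adjusted over the list alone; adjusted p = 0.000183) were also shifted upward. Both lost their call, at adjusted p = 0.73 and adjusted p = 0.584 with an estimated correlation. The blood pressure and cardiac trait genes had a median of -0.06 and a mean of -0.37 (1 of 15 called, Ephx2). Their camera adjusted p was 0.0134, and 0.186 with an estimated correlation. The mean was drawn down by Ephx2, whose probe was at background in SHRSP. The list was not called without SHR replicate 1 (adjusted p = 0.0763). Lymphocyte markers, whose score reached 3.75 on SHRSP replicate 4, had a median of 0.60 (0 of 8 called; adjusted p = 0.323).

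Of all genes, 59 were called between SHRSP and SHR, 34 higher and 25 lower, with 585 at an unadjusted p under 0.05 against 821 expected by chance. The split moved to 27 higher and 29 lower with quantile normalization and to 26 and 31 with scaling to the array median. Within the slide alone 39 were called. The count was 39 without SHR replicate 4, 39 without SHRSP replicate 1 and 38 without SHRSP replicate 2, and 880 with array weights.

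The 3rd question was how arteries of WKY with 2K1C or 1K1C differed from those of untreated WKY. No group was sham-operated, so effects of surgery and of hypertension cannot be told apart. Neither can an effect of age, if 6 weeks was the age at operation. After 2K1C 2 genes were called, both higher: Ier2, an immediate early gene, by 1.34 ± 0.20 (adjusted p = 0.0319, higher in 4 of 4 arrays), and an unnamed transcript at probe A_64_P035381 by 0.91 ± 0.14 (adjusted p = 0.0319). Immediate early genes as a list were shifted upward (median 1.12, 15 of 17 higher, 1 called and 5 adjusted over the list alone; camera adjusted p = 0.000149), and so were cell cycle genes (median 0.66, 23 of 24 higher, 0 called and 9 adjusted over the list alone; adjusted p = 2.44e-07). Both gave adjusted p = 0.836 with an estimated correlation. White adipocyte genes (median -0.85, 16 of 17 lower, 0 called and 5 adjusted over the list alone; adjusted p = 2.41e-05), fatty acid oxidation genes (median -0.73, 12 of 15 lower, 0 called and 6 adjusted over the list alone; adjusted p = 0.00173), brown adipocyte genes (median -1.07, 7 of 8 lower, 0 called and 3 adjusted over the list alone; adjusted p = 0.0143) and redox enzyme genes (median -0.33, 14 of 22 lower, 0 called; adjusted p = 0.0203) were shifted downward. These 4 lists also gave adjusted p = 0.836 with an estimated correlation. The brown adipocyte shift was not called without 2K1C replicate 1 or untreated WKY replicate 1 (adjusted p up to 0.121), nor the redox shift without 2K1C replicates 1 or 3 (adjusted p up to 0.149). Beside the adipocyte shifts, contractile smooth muscle genes had a median of 0.47 (15 of 17 higher, 0 called; adjusted p = 0.22).

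Many genes lay near the threshold in this comparison: 3617 had an unadjusted p under 0.05 against 821 expected by chance, and 301 an adjusted p under 0.1. Without 2K1C replicates 1, 2, 3 and 4 in turn 0, 1, 425 and 1 genes were called, and without untreated WKY replicates 2, 3 and 4 there were 0, 0 and 870. Ier2 lost its call without 2K1C replicates 1 or 4 or untreated WKY replicates 1, 2 or 3, and the unnamed transcript without 2K1C replicates 1 or 2 or untreated WKY replicates 2 or 3 (adjusted p up to 0.192 for both). Quantile normalization gave 8 genes, 3 higher and 5 lower; normexp gave 86, 30 higher and 56 lower. Array weights gave 4805 and the deposited values 0. The 2K1C arrays were on a slide of their own, so operation and slide cannot be told apart.

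After 1K1C, compared with untreated WKY on the same slide, limma called 0 genes, with 1493 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0663. A fit within the slide also gave 0, and the deposited value table gave 2. The 1K1C arrays lay in row 1 of the slide and the untreated WKY arrays in row 2, so operation and row cannot be told apart. Contractile smooth muscle genes were shifted downward (median -0.89, all 17 lower, 0 called; camera adjusted p = 5.35e-07, and 0.997 with an estimated correlation), with desmin (Des) at -1.56 ± 0.68. This shift was not called without 1K1C replicate 2 (adjusted p = 0.154), whose smooth muscle score was -3.12 while the others of its group lay between -1.05 and 0.13. Ion channel and calcium handling genes were lower (median -0.33, 19 of 26 lower, 0 called; adjusted p = 0.000165) and cell cycle genes higher (median 0.55, all 24 higher, 0 called; adjusted p = 5.35e-07), each with adjusted p = 0.997 with an estimated correlation. White adipocyte genes had a median of 0.46 (all 17 higher, 0 called; adjusted p = 0.0411, and 0.997 with an estimated correlation) and were not called without 1K1C replicates 1 or 2 or untreated WKY replicates 1 or 4 (adjusted p up to 0.782). Schwann cell and nerve genes had a median of -0.44 (6 of 9 lower, 0 called and 3 adjusted over the list alone; adjusted p = 0.0059, and 0.997 with an estimated correlation) and were not called without 1K1C replicate 2 or untreated WKY replicate 1 (adjusted p up to 0.132). Without untreated WKY replicate 4 the count of called genes was 205, without 1K1C replicate 3 it was 3 and without 1K1C replicate 4 it was 1; array weights gave 586.

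The renin-angiotensin list was not shifted against untreated WKY in either renovascular group or either strain (adjusted p between 0.208 and 0.655), and 0 of its 16 measured members were called there. Agtr1a, the angiotensin receptor, was at -0.71 ± 0.24 in 2K1C, -0.18 ± 0.24 in 1K1C, -0.40 ± 0.24 in SHR and -0.60 ± 0.24 in SHRSP. Angiotensin-converting enzyme (Ace) was at 0.77 ± 0.30 in 2K1C, 0.32 ± 0.30 in 1K1C, 0.77 ± 0.30 in SHR and 0.35 ± 0.30 in SHRSP. Genes of endothelin, nitric oxide and natriuretic peptide signalling (0 of 15 called) and of adrenergic receptors and sympathetic nerve were also not shifted in any comparison. Of the latter 14 genes 1 was called, the adrenergic receptor gene Adra1b in SHRSP at 0.81 ± 0.21 (adjusted p = 0.0496), and it kept its call only without untreated WKY replicate 4 (adjusted p up to 0.191).

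Between 1K1C and 2K1C limma called 0 genes at an adjusted p under 0.05, but 1167 at an adjusted p under 0.1 and 3536 at an unadjusted p under 0.05. White adipocyte genes were shifted upward in 1K1C (median 1.47, all 17 higher, 0 called and 16 adjusted over the list alone; camera adjusted p = 2.16e-09, and 0.508 with an estimated correlation), with Pparg, the master regulator of adipocyte differentiation, at 1.77 ± 0.46 and Adipoq at 1.36 ± 0.40. Contractile smooth muscle genes were shifted downward (median -1.42, all 17 lower, 0 called; adjusted p = 1e-07), and so were immediate early genes (median -0.98, 14 of 17 lower, 0 called and 7 adjusted over the list alone; adjusted p = 4.32e-05) and ion channel genes (median -0.46, 21 of 26 lower, 0 called; adjusted p = 0.000487). These 3 lists gave adjusted p = 0.508 with an estimated correlation. Fatty acid oxidation (median 0.86, 12 of 15 higher, 11 higher and 2 lower adjusted over the list alone; adjusted p = 0.00159) and brown adipocyte genes (median 1.39, 8 of 8 higher, 3 adjusted over the list alone; adjusted p = 0.0109) were shifted upward, with 0 called in either and adjusted p = 0.508 with an estimated correlation for both. Redox (median 0.37; adjusted p = 0.00957), interferon (median 0.33; adjusted p = 0.0327) and renin-angiotensin genes (median 0.52; adjusted p = 0.0485) were shifted upward with 0 called in each. The adjusted p with an estimated correlation was 0.508, 0.83 and 0.508. Their calls were also lost without 2K1C replicate 3 for redox, 2K1C replicates 1, 2 or 3 or 1K1C replicate 1 for interferon, and 2K1C replicates 2, 3 or 4 or 1K1C replicates 1 or 4 for renin-angiotensin genes (adjusted p up to 0.0622, 0.122 and 0.188). Without 1K1C replicate 4 the count of called genes was 1896, without 2K1C replicate 3 it was 296, and without 2K1C replicates 2 or 4 it was 1. The groups lay on different slides, so operation and slide cannot be told apart.

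**Figure D2:**
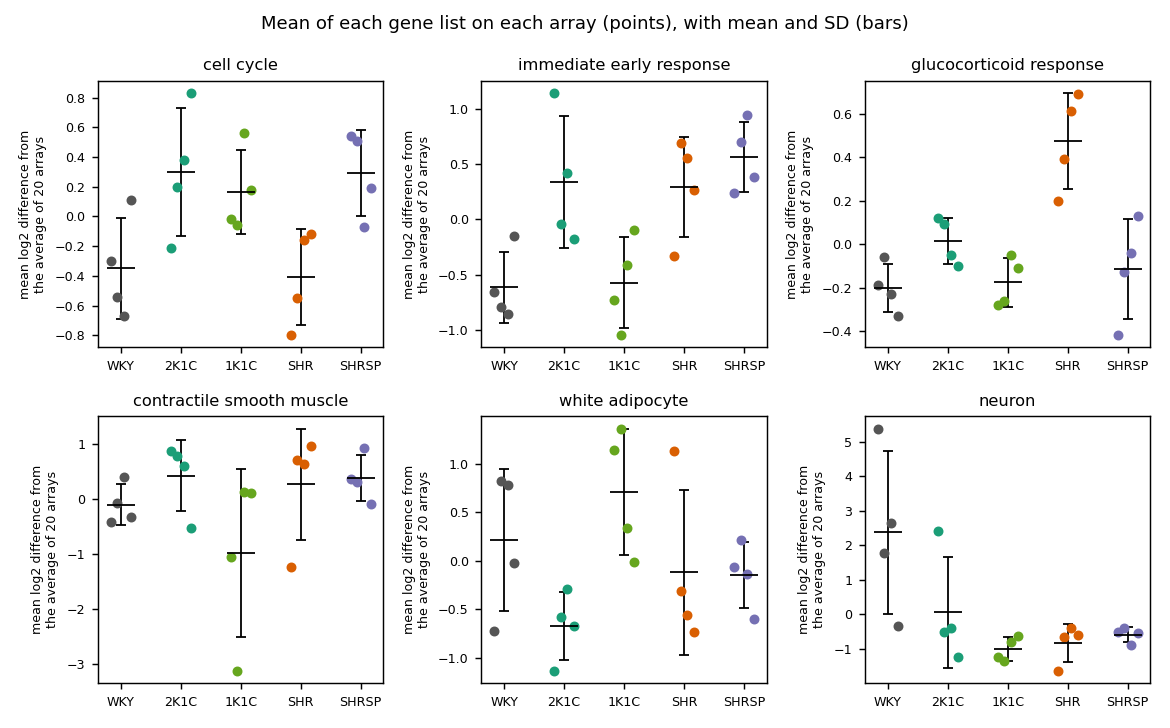
Mean of the measured members of 6 gene lists (y axis, log2 difference from the average of the 20 arrays) in untreated WKY, 2K1C, 1K1C, SHR and SHRSP (x axis), with 1 point per array and bars for the mean and SD of 4 arrays. Cell cycle scores averaged -0.41 in SHR and 0.29 in SHRSP, the lowest smooth muscle score was -3.12 on a 1K1C array, and the neuron list was added after the data had been seen.

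No gene was called the same way in both renovascular groups, nor in all 4 hypertensive groups (0 genes each in limma), which follows from the 0 genes called in 1K1C. At an unadjusted p under 0.05 there were 3617 genes in 2K1C and 1493 in 1K1C. Without untreated WKY replicate 4, 144 genes were called the same way in both renovascular groups and 129 in all 4 hypertensive groups, and with array weights 439 and 361. Across genes the log2 differences of 2K1C and 1K1C had a correlation of 0.43 (0.50 in simulation) and a covariance of 0.105 (0.059 in simulation). With different pairs of untreated WKY arrays as controls the correlation ranged from -0.224 to 0.264. Those of SHR and 2K1C had a correlation of 0.61 (0.50 in simulation) and a covariance of 0.177 (0.060 in simulation).

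The last question was how the inherited forms differ from the renovascular ones. Between the mean of SHR and SHRSP and the mean of 2K1C and 1K1C 519 genes were called, 237 higher and 282 lower in the inherited forms, with 2897 at an unadjusted p under 0.05. The deposited value table gave 589 higher and 96 lower, and array weights gave 3536 genes. In the trait list 2 of 15 members were called, Endog at -2.00 ± 0.14 and Ephx2, for which no size is given because its probe was at background in SHRSP. Ephx2 in SHR, at -1.27, lay between 2K1C at -2.01 and 1K1C at -0.45, so its call belonged to SHRSP alone. Called members of other lists included the inducible chaperone gene Hspa1b at 2.83 ± 0.61. Chaperone genes as a list were shifted upward in the inherited forms (median 0.28, 15 of 16 higher, 1 called; camera adjusted p = 5.17e-05, and 0.131 with an estimated correlation). Smooth muscle (median 0.59, all 17 higher; adjusted p = 0.00316), immediate early (median 0.56; adjusted p = 0.00411), pancreas and intestine (median 1.57; adjusted p = 0.00618) and ion channel genes (median 0.30; adjusted p = 0.0132) were shifted upward, with 0 called in each. These 4 gave adjusted p = 0.776 with an estimated correlation. For smooth muscle, immediate early and ion channel genes, 1K1C had the lowest mean scores of the 4 hypertensive groups, at -0.98, -0.57 and -0.42. In 2K1C these scores were 0.43, 0.33 and 0.13, beside 0.27, 0.29 and 0.17 in SHR and 0.38, 0.56 and 0.16 in SHRSP. In untreated WKY they were -0.1, -0.62 and -0.04. The immediate early score of 1K1C was thus level with that of untreated WKY on the same slide. Cell cycle (median -0.33; adjusted p = 0.00331) and erythroid genes (median -0.66; adjusted p = 0.0143) were shifted downward, also with 0 called, and both gave adjusted p = 0.776 with an estimated correlation. In the cell cycle shift SHR was the low group, at a mean score of -0.41, while SHRSP at 0.29 was level with 2K1C at 0.30 and 1K1C at 0.16. Untreated WKY was at -0.35, so SHR was level with it and the other groups were higher. The smooth muscle shift was not called without 1K1C replicate 2 (adjusted p = 0.0803), the ion channel shift without 2K1C replicate 4 or 1K1C replicate 2 (up to 0.0702), the cell cycle shift without 2K1C replicate 4 (0.0522) and the erythroid shift without 2K1C replicate 4 or SHRSP replicate 4 (up to 0.062). Strain and slide cannot be told apart in this comparison.

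**Figure D3:**
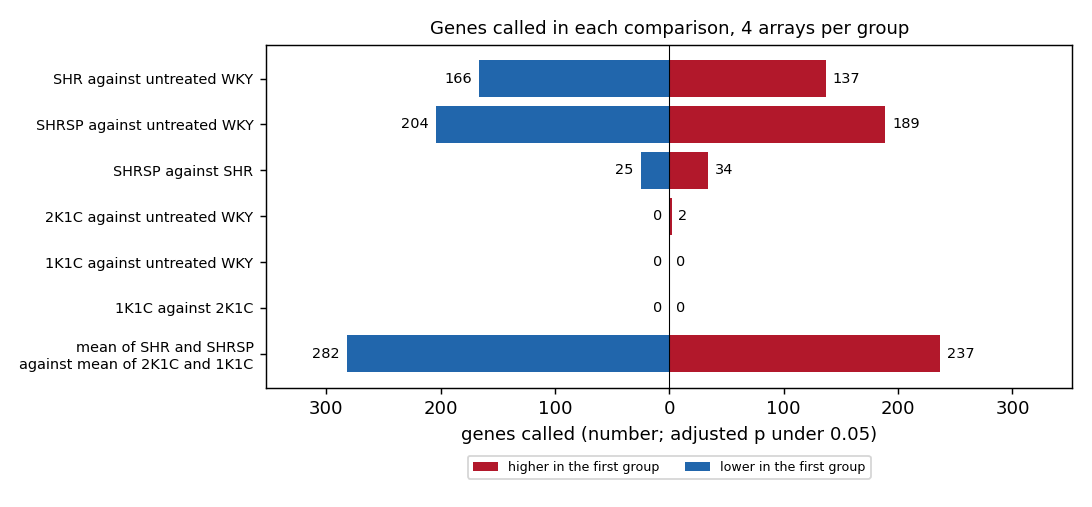
Number of genes called (x axis; limma, adjusted p under 0.05) in each of the 7 comparisons (y axis), higher in the first-named group to the right and lower to the left. The comparisons that involve SHR or SHRSP held 59 to 519 called genes, and those among WKY groups 0 to 2. This order depends on the threshold. At an unadjusted p under 0.05 in limma, SHR and SHRSP against untreated WKY held 2294 and 2735 genes. For 2K1C and 1K1C against untreated WKY and 1K1C against 2K1C these were 3617, 1493 and 3536.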

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

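Of the tests here, those on the 4 largest strain differences, on slides, on nerve tissue and on fat were chosen only after the result was seen; the splits of the samples and the test of other probes were set before.

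Between SHRSP and SHR, whose difference is also the difference of their effects against untreated WKY, the named genes called were Vegfb (9.06), Zfp597 (2.83), Abca9 (2.63), Rgs11 (2.21), Pcdhga8 (1.91), Rhd (1.90), Pxmp4 (1.86) and Serhl2 (1.85) among those higher in SHRSP. Those lower were Hba-a3 (-6.76), Agtrap (-4.78), Ephx2 (-4.34), Micb (-3.52), Samd14 (-3.03), Depp1 (-1.75), Sgca (-1.67), Zfp108 (-1.54) and Tsc22d3 (-0.90), all as fitted log2 differences. Those of Vegfb, Abca9, Hba-a3, Ephx2, Micb, Samd14 and Zfp108 include a group at background signal, so they are no exact sizes and no ranking, and the bounds are the at least 139-, 2.46-, 35.7-, 20.2-, 6.76-, 2.48- and 1.97-fold differences. Lists that differed were cell cycle (median 0.80), cholesterol synthesis (0.26), interferon response (0.23), glucocorticoid response (-0.63) and the blood pressure and cardiac trait genes (-0.06). Between 1K1C and 2K1C the lists that differed were white adipocyte (1.47), brown adipocyte (1.39), fatty acid oxidation (0.86), renin-angiotensin (0.52), redox (0.37), interferon (0.33), ion channels (-0.46), immediate early (-0.98) and smooth muscle (-1.42). With an estimated correlation in camera, 1 of these 14 list differences held, that of glucocorticoid response.

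A pattern across the strain comparisons is that a few probes changed from well above background to near background in 1 strain. A base difference between the strains under a 60-mer probe could lower its signal with no change in RNA. For Vegfb, Hba-a3, Agtrap and Ephx2 0 of the 4 genes had another detected probe, so a probe effect and a change in RNA cannot be told apart there. The same limit holds for the other strain genes named above as called whichever single array was left out, Endog and Afp among them. None of these had another detected probe. Of the 696 calls in SHR or SHRSP against untreated WKY, 102 were of genes with another detected probe. Of the 112 differences at those probes, 72.3% went the same way with at least 50% of the tested probe's difference. Many probes count there for both strains: over the 82 distinct probes, each with its mean over comparisons, the share was 69.5%, with 76.7% of 43 in SHR and 69.6% of 69 in SHRSP. The pooled shares lie below the 75% set in advance to exclude a probe effect as the main cause and above the 50% that would have pointed to it. No WKY array lay on the slide of SHR and SHRSP, and the 2 genes called between the 2 WKY groups on different slides, 2K1C and untreated, do not separate strain from slide.

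A list of neuron genes, added after the data were seen and with members already known to differ, was lower in SHR and SHRSP than in untreated WKY. The fixed list of Schwann cell and nerve genes was not shifted in either (camera adjusted p = 0.255 and 0.493). The median of 11 measured neuron genes was -2.97 in SHR, -3.02 in SHRSP, -2.17 in 2K1C and -3.37 in 1K1C, each against untreated WKY. The value of -3.37 in WKY rats on the same slide goes with a hypothesis of nerve or ganglion tissue in some untreated WKY samples. The neuron genes of SHR differed from those of 1K1C by a median of 0.14 (SD over genes 0.76), and the noradrenergic neuron genes by 0.7 (SD 0.63). Low neuron genes were thus not limited to the hypertensive strains. Because SHR and 1K1C differ in slide and operation as well as strain, this does not decide whether the strains differ. Neuron scores were 5.38, 1.78, 2.64 and -0.33 on untreated WKY replicates 1 to 4 and 2.41 on 2K1C replicate 1, against -1.64 to -0.40 on the other arrays of 2K1C, 1K1C, SHR and SHRSP. An effect of the operations in 2K1C and 1K1C that resembles the strain difference was not tested and stays open, and artery expresses some of these genes. The neuron list shares 4 members with the fixed list of Schwann cell and nerve genes.

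White adipocyte genes were higher and smooth muscle genes lower in 1K1C than in 2K1C. If the samples held different shares of perivascular fat, both scores should move in opposite ways within groups too. Over the 20 arrays, deviations from the group means had a Pearson r of -0.53 (permutation p = 0.055) and a Spearman rho of -0.38 (permutation p = 0.16), 2 relations in all, and r was -0.50 without SHR replicate 1 and untreated WKY replicate 1. The test therefore leaves a share of fat, a change in adipocytes and an effect of the operation open. The number of slides that hold both 1K1C and 2K1C was 0, so operation and slide cannot be told apart.

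A sample far from the rest of its group was seen for 8 of 145 list scores in a group, 0 of 15 array quality measures in a group and 10 of 185 values of a named gene in a group, by Dixon's ratio of the gap to the range, and chance gives about 1 in 20. SHR replicate 1 stood apart for the scores of smooth muscle (0.854), extracellular matrix (0.884), redox enzymes (0.883), mesothelium (0.908) and Schwann cell and nerve (0.846), and for Snph (0.952). On 2K1C replicate 4 the endothelium score (0.977) and Rgs11 (0.862) stood apart, on 2K1C replicate 1 Caly (0.846), Acot5 (0.916) and Syp (0.905). On SHRSP replicate 2 this held for the brown adipocyte score (0.918), and on SHRSP replicate 4 for Pip (0.86). On untreated WKY replicate 1 it held for the adrenergic and sympathetic score (0.901) and Agtrap (0.851), on untreated WKY replicate 4 for Pip (0.859), and on 1K1C replicate 3 for Zfp597 (0.846).

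The 8 arrays of a comparison split into 4 and 4 in 35 ways. For SHRSP against untreated WKY 1 of the 35 splits called as many genes as the real split (393, highest other 5). For SHRSP against SHR it was 1 too (59, highest other 1). In both, that 1 was the real split itself, which is the smallest share that 35 splits can give. Both counts stood above those of every other split, but with this floor and no adjustment over comparisons the splits do not exclude chance. For SHR against untreated WKY 3 of 35 splits called as many as 303, with a highest other of 1115, so chance is not excluded for that count. The split with 1115 genes exchanged SHR replicate 1 with untreated WKY replicate 4, which points to a structure of the samples beyond strain. A split with 773 genes exchanged SHR replicate 1 with untreated WKY replicate 1, so both turn on SHR replicate 1. The split with 1115 genes is no exchange of labels for strain-marked genes: Vegfb was -7.74 on SHR replicate 1 and 1.27 on untreated WKY replicate 4. For 2K1C against untreated WKY 5 of 35 splits called at least 2 genes (highest other 126), so chance is not excluded there. With 0 real calls, all 35 splits of 1K1C against untreated WKY (highest other 258) and of 1K1C against 2K1C (highest other 142) call as many by construction, which decides nothing about chance. The highest value for 2K1C against untreated WKY is many times its real count and points to a structure of the samples too. For the inherited against the renovascular forms only the real split among 100 called 519 (highest other 98), which is the smallest share that 100 splits can give. Real splits that follow the slides are those of every comparison except 1K1C against untreated WKY and SHRSP against SHR. The real splits of those comparisons follow the rows of a slide instead.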

How the results depend on the processing

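Leaving out the arrays that stood apart and leaving out the farthest array of each group were chosen after seeing the data, the latter after the counts of the former were known; the other alternatives were set before. Arrays carry no counts, and genes near background on some arrays set the limit: detection on all 20 arrays gave 186 genes for SHR and 29 for SHRSP against SHR. No result changed direction while called. Across scaling and detection alternatives 44 to 60 of the list shifts were called against 48, and 1 with an estimated correlation. Of the 74 named calls 35 held in every fit without 1 array, and of the 48 list shifts 26. A fit of the compared groups alone lost 39 of the 74 named calls, and the deposited value table lost 26. Where a count moved the cause was not tested. A fit of the compared groups alone, a 2-fold minimum and left-out arrays use fewer samples or genes. Some counts nevertheless rose with an array left out, to 669 for SHR and 870 for 2K1C without untreated WKY replicate 4. Counts are in the order SHR, SHRSP and 2K1C against untreated WKY unless named.

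Quantile normalization gave 8 genes for 2K1C, and normexp 86 for 2K1C and 1 for 1K1C against 2K1C. The deposited value table, with no scaling between arrays, gave 120, 207 and 0, with 39 for SHRSP against SHR, 2 for 1K1C and 79 shared by SHR and SHRSP. Scaling to the array median shifted the median of all genes by 0.121 for SHR and 0.182 for 1K1C against untreated WKY, and the value table by 0.173 for SHRSP, 0.169 for SHRSP against SHR, -0.19 for 2K1C and 0.229 for the inherited against the renovascular forms. The trend and robust options gave 1 gene for 2K1C. Array weights gave 7659, 5540 and 4805, with 880 for SHRSP against SHR, 586 for 1K1C and 3536 for the inherited against the renovascular forms. They gave 4583 shared by SHR and SHRSP, 439 by 2K1C and 1K1C and 361 by all 4 groups. Fits of the compared groups alone gave 102, 161 and 0, with 39 for SHRSP against SHR and 57 shared by SHR and SHRSP. A 2-fold minimum gave 197, 256 and 1, with 169 for the inherited against the renovascular forms and 118 shared. Without the 2 arrays that stood apart on a marker list of another tissue or cell type (SHR replicate 1 and SHRSP replicate 2; 2K1C replicate 4 and untreated WKY replicate 1, apart on endothelial and sympathetic scores, stayed in) there were 0 genes for 2K1C, 29 for SHRSP against SHR and 815 for 1K1C against 2K1C. Without the array of each group farthest from its mean over all genes (2K1C 4, 1K1C 2, untreated WKY 1, SHR 1 and SHRSP 4) there were 1748, 827 and 1298, 61 for SHRSP against SHR, 0 for 1K1C, 2 for 1K1C against 2K1C, 600 shared by SHR and SHRSP and 75 list shifts.

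Without 1 array at a time the ranges were 124 to 669 for SHR, 172 to 911 for SHRSP, 38 to 54 for SHRSP against SHR, 0 to 870 for 2K1C, 0 to 205 for 1K1C, 0 to 1896 for 1K1C against 2K1C and 367 to 777 for the inherited against the renovascular forms. They were 87 to 497 shared by SHR and SHRSP, 0 to 144 by 2K1C and 1K1C, 0 to 129 by all 4 groups, and 44 to 63 list shifts. The replicate numbers did not pair the samples: 13 of 40 same-numbered pairs had a correlation of deviations over 0.1 (median -0.02), and 5 of 20 samples correlated best with their own number. With the replicate block the counts were 285, 363 and 2, with 51 for SHRSP against SHR, 0 for 1K1C, 0 for 1K1C against 2K1C, 505 for the inherited against the renovascular forms, 176 shared and 51 list shifts; 11 of the 74 named calls were lost. Slide as a fixed block leaves the comparisons within a slide unchanged by construction, and slide as a random block was not run, since no group spans slides.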

Other observations

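The noradrenergic neuron list was chosen after the data had been seen. Markers of other cell types varied between arrays of a group. Lymphocyte scores ranged from -1.80 to 4.86 in 2K1C and from -1.62 to 3.75 in SHRSP, and from -0.65 to 0.01 in 1K1C. Mesothelial scores ranged from -0.67 to 2.83 in untreated WKY and from -0.83 to 2.78 in SHR, and pancreas and intestine scores from -3.91 to 3.24 in SHRSP. Macrophage, lymphocyte, cytokine, antigen presentation, circadian clock, lymphatic endothelium, mesothelium and striated muscle lists had no camera adjusted p under 0.05 in any of the 7 comparisons. Striated muscle scores were 0.42 ± 0.06 (SD, n = 4) in SHRSP and -0.06 ± 0.20 in SHR. Of 6 measured noradrenergic neuron genes the median difference from untreated WKY was -1.5 in SHR, -1.41 in SHRSP, -0.82 in 2K1C and -1.89 in 1K1C, with a score of 5.50 on untreated WKY replicate 1.

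Other genes taken by the naming rule changed as well. In SHR, Alb was at 2.17 ± 0.54, the neuropeptide gene Nts at 2.15 ± 0.51 and the tight junction gene Cldn19 at 4.55 ± 1.01 relative to untreated WKY, and Ccl12 was at least 4.71-fold lower. Each lost its call without some single array (adjusted p up to 0.123, 0.134, 0.119 and 0.0539). For Ccl12 these were SHR replicates 2 and 3, for Cldn19 and Nts untreated WKY replicates 2 and 3 and SHR replicates 2, 3 and 4, and for Alb each array except untreated WKY replicate 4. The other detected probe of Cldn19 differed by 2.53.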
